A study of Nicotiana benthamiana with 8 samples.

How the data were processed

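Gene expression was measured in whole Nicotiana benthamiana seedlings, 21 days after germination, grown on half-strength Murashige and Skoog agar with nothing added (control), with GR24 at 1e-07 M, with smoke water diluted 1:1000, or with KAR1 at 1e-07 M. GR24 is a synthetic strigolactone analogue, and KAR1 is the butenolide of smoke also called karrikinolide. Each of the 4 groups had 2 arrays, 8 in all, named by group and replicate number. The series' design text gives 2 independent trials and the growth protocol gives 3, and the labels do not say which array came from which trial. The p-values therefore measure the spread between arrays of a group, which may be technical.

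Total RNA was labelled with Cy3 and hybridised 1 sample per array, per the labels' protocols. The arrays carry probes designed for tobacco (Nicotiana tabacum), per the file headers, so a probe can fit its N. benthamiana transcript imperfectly. Values come from the spot intensity (the processed signal) in the scanner files, which Agilent Feature Extraction 9.5.3.1 had corrected for background and for trends across the array, per the file headers, giving dim spots a substitute value. These deposited intensities were not normalized between arrays. MAS5 is named in the submitters' processing notes. What it was applied to is not given in the sources used here. The spot flags (well above background, saturated, outlier; a unit of other kind, yes or no) are as deposited by the authors' scanner software, per the file headers. The authors' series matrix holds 1 processed log2 value per probe and array. Its columns correlated at r above 0.9999 with the same array's log2 scanner signal after scaling, taken minus each probe's median over all arrays. That settles scale and direction and points to values centred per probe. The centring of the matrix itself stays unstated. Its column medians were 0.0244 and 0.0352 (control), -0.119 and -0.0335 (GR24), -0.146 and -0.0535 (smoke water), and 0.0951 and 0.144 (KAR1).

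Each array held 45220 spots, of which 1417 were controls and were left out. The signal was turned to log2, and each array's 75th percentile was subtracted. Spots flagged as outliers, 6 to 16 per array, were set to missing, and 44 extra copies of probes were averaged, leaving 43759 probes. A probe was tested if it was well above background on both arrays of at least 1 group, which left 22952 probes with 43 values missing. Among these, 5207 carried a gene description in the files. The others are known only by sequence names, and no table of newer gene names was used here. Tests were made with limma 3.58.1 in R 4.3.3 (with the data.table package, version 1.17.8): 4 group means over all 8 arrays, with 4 residual degrees of freedom, default moderated variances (2.55 prior degrees of freedom, prior SD 0.24), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. All 6 pairwise comparisons and an F test across groups were made. Standard errors are limma's moderated ones, and n is 2 arrays per group throughout. An exact permutation test of 2 arrays against 2 cannot go below 0.333, so no single-gene permutation test is given. Fold changes of a probe that was not well above background on every array of the dimmer group are bounds: the brighter group's mean is set against the dimmer group's mean of, per array, the higher of the lowest signal well above background and the probe's own signal, and the ratio is written "at least N-fold". No fold is given where the bound is under 1 or where neither group measured the probe on both arrays.

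27 gene lists were fixed as text patterns on gene names and descriptions. They cover light harvesting and photosystems, Calvin cycle, chlorophyll synthesis, strigolactone and karrikin pathway, gibberellin, auxin response, abscisic acid and dehydration, ethylene, cytokinin, brassinosteroid, cell wall loosening, cell cycle and histones, cytosolic ribosomal proteins, pathogenesis-related and defence, jasmonate and wounding, phenylpropanoid and flavonoid, detoxification enzymes, oxidative stress enzymes, heat shock proteins, light signalling and clock, nitrate and phosphate, sugar and starch, lipid transfer and cuticle, root-enriched nicotine genes, seed storage, flower and pollen, and organelle-encoded genes. With the brightest probe of each of 20753 gene names, 24 lists had at least 5 genes and were tested with limma's camera (preset inter-gene correlation 0.01), adjusted over 96 tests, 24 lists in 4 comparisons. The same test was run with an estimated correlation. Members were checked by hand after the values were seen, and 9 of 62 light harvesting, 24 of 167 ribosomal and 5 of 9 organelle-encoded members turned out to be other kinds of genes.

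Genes are named by a fixed rule: described probes past the threshold with no overlap of the groups, at most 12 per direction, filled up to 6 by smallest unadjusted p among those with an absolute log2 difference of at least 1, and 4 members per list by smallest unadjusted p. The value of 1 such member is not reported here. The groups, tests, lists, naming rule and 19 alternatives were chosen before the data were examined. Another 8 alternatives were added after seeing the data: spots in locally bright areas set to missing, a block for 2 array sets told apart by eQC-40 control spots, the combination of both, the block and the missing spots for the shared response (2 alternatives), a crossed pairing of replicate numbers, both KAR1 arrays left out, and mismatched list members left out. A spot counted as locally bright where at least 10% of the other spots within 4 rows and 4 columns lay over 2 log2 units above their own median across arrays. The arrays came on 2 slides, each scanned at its own time: control and smoke water on slide 1 (scan 1), GR24 and KAR1 on slide 2 (scan 2). Comparisons between slides cannot be told apart from the slide.

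The procedure was tested on simulated data made from the real probes' means and spread (22909 probes per comparison). With true log2 differences of 1, 2 and 4 it recovered 11.9%, 44.8% and 89.4% of changed probes for GR24 against control, 5.97%, 73.1% and 83.3% for smoke water against control, and 5.97%, 55.2% and 92.4% for KAR1 against control. False calls were 5 of 102, 6 of 114 and 7 of 109. A light harvesting list shifted by 0.5 was called in 2 of 2 comparisons, with 0 of 94 other tests called by limma's camera. The simulated arrays held no correlation between genes and no array sets, so they do not show how the list test behaves with either. Figures were drawn with Python 3.11.15, matplotlib 3.10.9 and numpy 2.4.6.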

Results

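Transcript levels were measured on 8 single-colour tobacco arrays hybridised with RNA from whole N. benthamiana seedlings, 2 arrays for each of 4 groups: control, GR24, smoke water and KAR1. Between 22312 and 23529 of the 43759 probes, 51.0% to 53.8%, were well above background on an array. The 75th percentile of the intensity lay between 283.9 and 390.3, against a median local background of 39 to 42, and 0 or 1 spot per array was saturated. Pairs of arrays correlated at 0.970 to 0.995 across probes, which are not independent replicates. Among control, GR24 and smoke water, arrays sharing a replicate number correlated at 0.988 to 0.995. The 2 arrays of each of these groups correlated at 0.978 to 0.983, so the spread in their tests includes the difference between replicate numbers. The SD of the log2 difference between both arrays of a group was 0.63 for control, 0.59 for GR24, 0.54 for smoke water and 0.61 for KAR1. The number of arrays limits the precision: the median 95% interval of a difference reached 0.61 log2 units to each side.

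The 8 arrays split on something other than their group. The eQC-40 positive control spots lay at 14.82 to 15.10 log2 on 3 arrays (replicate 1 of control, GR24 and smoke water; set 1) and at 15.92 to 16.21 on the other 5 (set 2), which include both KAR1 arrays. The spike-in RNAs named E1A did not split so: their set means differed by 0.30 log2 units at most. KAR1 2 was placed in set 2 by its eQC-40 spots alone. Across probes it correlated at 0.9722 to 0.9795 with the other set 2 arrays, and at 0.9749 to 0.9761 with those of set 1. Between the sets, 2157 probes differed by limma's test (7252 at an unadjusted p under 0.05). Light harvesting genes had a median log2 difference of 0.74, set 2 minus set 1 (adjusted p = 4.05e-16 with the preset correlation, 0.620 with an estimated correlation), chlorophyll synthesis genes 0.64 and root-enriched nicotine genes 1.00. Control and smoke water shared slide 1, and GR24 and KAR1 shared slide 2. A slide block leaves the comparisons within a slide as they are, with 0 probes for smoke water minus control (291 at an unadjusted p under 0.05) and 8 for KAR1 minus GR24. Slide and group cannot be told apart in the other comparisons.

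GR24 against control asks what the strigolactone analogue changed in seedlings grown on it. A single undescribed probe, A_95_P094308, fell, by 4.80 on the log2 scale (SE 0.26, n = 2 arrays per group, limma adjusted p = 0.017), at least 7.40-fold lower in GR24. The cystinosin homolog (A_95_P028206), whose animal counterpart exports cystine from lysosomes, had a log2 difference of -3.13 (SE 0.25, adjusted p = 0.085), at least 2.96-fold lower, without passing. In smoke water these probes had log2 differences of -0.59 and -0.43 from control. Described probes filled in by unadjusted p, none of which passed, were higher for proteasome subunit beta type 6 (1.54, at least 2.84-fold, and 1.13 with a locally bright spot on GR24 2 missing), origin recognition complex subunit 6-like (1.47, 2.77-fold), the 14-3-3 protein c-2 (1.42, at least 2.67-fold, 1 of 2 control arrays above background), an FLK-like RNA-binding protein (1.43, at least 1.14-fold), SRP19 (1.04, 2.05-fold) and a peroxidase precursor (2.13, no fold, 1 of 2 GR24 arrays above background). They were lower for adenylate kinase family-like protein (-1.86, 3.62-fold), ribosomal protein L7 (-1.09, 2.14-fold), COP1-like protein (2.01-fold), a histone H2B-like protein (-1.59, at least 1.97-fold) and a rice P0005C02.108-like gene (-2.05, 4.15-fold, SE 1.14). Of 22952 probes, 642 had an unadjusted p under 0.05, where 1147.6 would by chance, and the groups did not overlap at 26.2% of probes against 33.3% by chance. Chance values here and below take the arrays as interchangeable, which the array sets go against. A lower count is therefore not evidence of fewer differences. With the array sets as a block, chosen after seeing the data, the same probe alone passed (1388 at an unadjusted p under 0.05), but with the replicate numbers as a block 0 passed by limma (952). GR24 against control also gave 0 with normexp background correction (276 at an unadjusted p under 0.05), normexp and quantile normalization (428), no dim filter (1484), probes above background on all 8 arrays (422), only the 2 groups (594) or both KAR1 arrays left out (725). The filter on all 8 arrays leaves A_95_P094308 untested, so that 0 does not bear on its call. The call ended without any of the 8 arrays in turn (0 probes by limma each, 336 to 725 at an unadjusted p under 0.05).

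The light signalling and clock list shifted down in GR24, with a median log2 difference of -0.17 (17 of 20 genes lower, adjusted p = 0.0110 with the preset correlation, adjusted p = 0.970 with an estimated correlation). None of its members passed alone, adjusted over the list alone or over all probes. COP1-like protein, of a family of ubiquitin ligases that repress light responses, was 2.01-fold lower (log2 SE 0.39), and COP1-interacting protein CIP7 had -0.72 (SE 0.22), at least 1.58-fold lower with 1 of 2 GR24 arrays above background. The shift did not pass without control 1 (-0.14, adjusted p = 0.246) or GR24 2 (-0.04, 0.606), and was -0.38 without control 2 and -0.34 without GR24 1. It ended with normexp background correction (-0.13, 0.0518) and with no dim filter (-0.22, 0.293). The same list had a median of -0.14 within array set 1 and -0.30 within set 2, on 1 array against 1 each. Of the strigolactone and karrikin pathway list only carotenoid cleavage dioxygenase 1B (A_95_P010596) was measured, with 0.06 (SE 0.21) in GR24, -0.09 in smoke water and 0.34 in KAR1, none of which passed. This enzyme belongs to the family that holds strigolactone synthesis enzymes.

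Smoke water against control asks what the whole smoke extract changed. No probe passed (0 by limma, 291 at an unadjusted p under 0.05, 22.5% of probes without overlap against 33.3% by chance). By limma 0 passed with the array sets as a block (859 at an unadjusted p under 0.05) or the replicate numbers as a block (492). The described probes with the smallest unadjusted p were higher for a plant gene described only as catalytic (A_95_P208387; 1.95, SE 0.43, at least 1.34-fold), the FLK-like protein (1.40, no fold, 1 of 2 smoke water arrays above background), NtEIG-E80 (2.11, at least 1.48-fold), an ATP8-like gene (1.51, at least 1.43-fold), the 14-3-3 protein c-2 (1.03, at least 2.04-fold) and a low temperature and salt responsive protein (1.33, at least 2.02-fold), each with an adjusted p of 1.00. No described probe with a log2 difference of -1 or below met the same criteria.

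Genes for cytosolic ribosomal proteins shifted down in smoke water, with a median log2 difference of -0.09 (131 of 167 genes lower, adjusted p = 0.00474 with the preset correlation, 0.970 with an estimated correlation). With 24 members left out that are plastid or bacterial-type ribosomal proteins, a choice made after the values were seen, the median was -0.07 (0.0284). The median turned to 0.0066 (adjusted p = 0.968) without control 2, was -0.05 (0.191) without smoke water 1 and -0.21 without control 1. Quantile normalization (-0.04, 0.165), the same with normexp (-0.05, 0.165) and no dim filter (-0.10, 0.828) also ended the call. Within array set 1 it was -0.02 and within set 2 it was -0.17. Phenylpropanoid and flavonoid genes shifted up, with a median of 0.13 (22 of 33 higher, adjusted p = 0.0296 with the preset correlation, 0.970 with an estimated correlation). Among genes chosen after their values were seen, phenylalanine ammonia-lyase, which opens the pathway, had 0.40 (SE 0.24) at A_95_P176332 and 0.34 (SE 0.42) at PAL1, and hydroxycinnamoyl CoA quinate transferase 0.88 (SE 0.70). Cinnamoyl-CoA reductase had 0.69 (SE 0.34), and caffeoyl-CoA O-methyltransferase 3 had 0.23 (SE 0.66) with 1 of 2 arrays of each group above background, so no fold is given. The shift did not pass without control 1 (0.21, 0.138), control 2 (0.13, 0.197) or smoke water 2 (0.01, 0.900), was 0.35 without smoke water 1, and with the array sets as a block was 0.13 (0.0616). With no dim filter it was 0.0015 (0.293). Within set 1 it was 0.01 and within set 2 it was 0.24. No member of either list passed alone, adjusted over the list alone or over all probes.

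KAR1 against control asks what the smoke-derived butenolide changed on its own. It gave 13 probes, 9 higher and 4 lower (limma, 1329 at an unadjusted p under 0.05, 32.6% without overlap against 33.3% by chance). The glycine-rich protein-like gene A_95_P201077 rose by 4.75 log2 units (SE 0.39, adjusted p = 0.028), at least 6.14-fold. The cystinosin homolog fell by 3.12 on the log2 scale (SE 0.25, adjusted p = 0.028), at least 2.26-fold lower. These were the described ones. Of undescribed probes, A_95_P159872 rose by 3.86 (SE 0.22, adjusted p = 0.012), at least 3.31-fold, and A_95_P231819 by 4.03 (SE 0.22, adjusted p = 0.012), at least 3.55-fold. A_95_P094308 fell by 4.15 (SE 0.26, adjusted p = 0.014), at least 5.65-fold lower, and A_95_P069925 by 2.50 (SE 0.22, adjusted p = 0.032), 5.67-fold lower. With the array sets as a block 2 probes passed, both higher, and none of the 4 lower ones did: A_95_P028206, the cystinosin homolog, had -3.01 (adjusted p = 0.080) and A_95_P094308 -4.04 (0.057). All 9 higher probes were not well above background on any control, GR24 or smoke water array, as the plot of the called probes shows, while the 4 lower ones had log2 differences of -4.80, -3.13, -2.09 and -1.80 between GR24 and control, of which the first passed. With the replicate numbers as a block 3 passed, all higher. By limma 0 passed with normexp background correction (912 at an unadjusted p under 0.05), normexp and quantile normalization (1189), no dim filter (2087), probes above background on all 8 arrays (1068), only the 2 groups (938), or trend and robust variances (1279). The filter on all 8 arrays leaves the 9 higher probes, A_95_P094308 and the cystinosin homolog untested, so it does not bear on their calls. Without control 1, control 2, smoke water 1 or smoke water 2, 0 probes passed by limma (869, 1239, 1187 and 1187 at an unadjusted p under 0.05). Without either GR24 array 5 passed, without KAR1 1 18 passed and without KAR1 2 15, of which 4, 7 and 9 were among the 13.

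**Figure D1:**
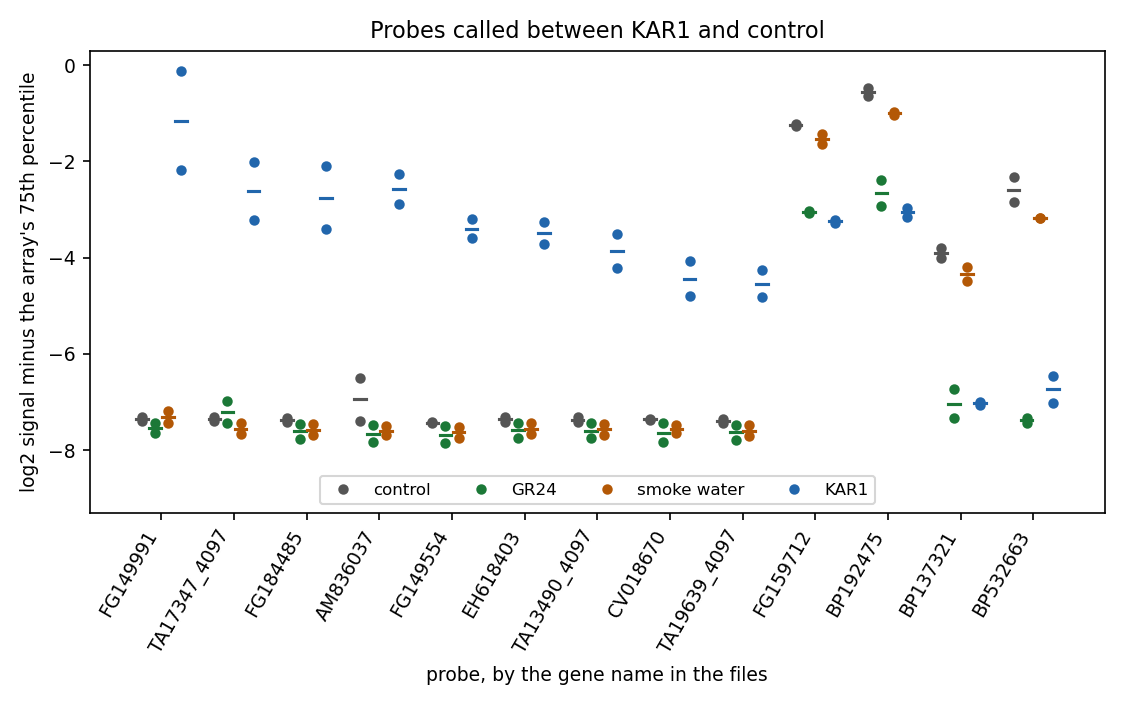
Log2 signal minus the array's 75th percentile (y axis) at the 13 probes called between KAR1 and control (x axis, by gene name in the files), with a point per array and a bar at each group's mean. The 9 higher probes rise above the floor on KAR1 arrays alone, and the 4 lower ones lie low in GR24 and KAR1.

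The 9 higher probes lay close together, in rows 177 to 199 of 532 and columns 29 to 67 of 85. In that region spots of many unrelated probes were bright on both KAR1 arrays. Of the 9, 6 (66.7%) lay where at least 10% of neighbouring spots were bright on both KAR1 arrays, against 0.828% of all tested probes (190; two-sided Fisher's exact test, p = 2.45e-11). These areas were looked for after the calls were seen. They are defined by brightness on the same KAR1 arrays that gave the calls. Called spots that lie close count as each other's neighbours, so Fisher's test does not weigh independent spots. With such spots set to missing 7 probes passed, 3 higher and 4 lower, among them the cystinosin homolog (adjusted p = 0.041) and A_95_P094308 (0.020). The higher ones were A_95_P231819 (4.03, adjusted p = 0.014) and A_95_P274583 (4.37, 0.041), both among the 9, and A_95_P073890 (4.52, 0.048). The first 2 had no locally bright spot and kept their values, while the 6 lost both KAR1 values and could not be called. A_95_P073890 lies at row 201 and column 62, at the edge of the region. A_95_P231819 also passed with the array sets as a block (3.93, 0.033) and with both (3.93, 0.036). Other probes were matched to a called one by a shared stretch of bases, sequence name or gene name. A_95_P235364, matched to the glycine-rich protein-like probe, had a log2 difference of 0.23. It lay at -3.32 in control and the called probe at -7.36, so both may not read the same transcript. The probe matched to A_95_P159872, not well above background on both arrays of any group, had 0.15.

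**Figure D2:**
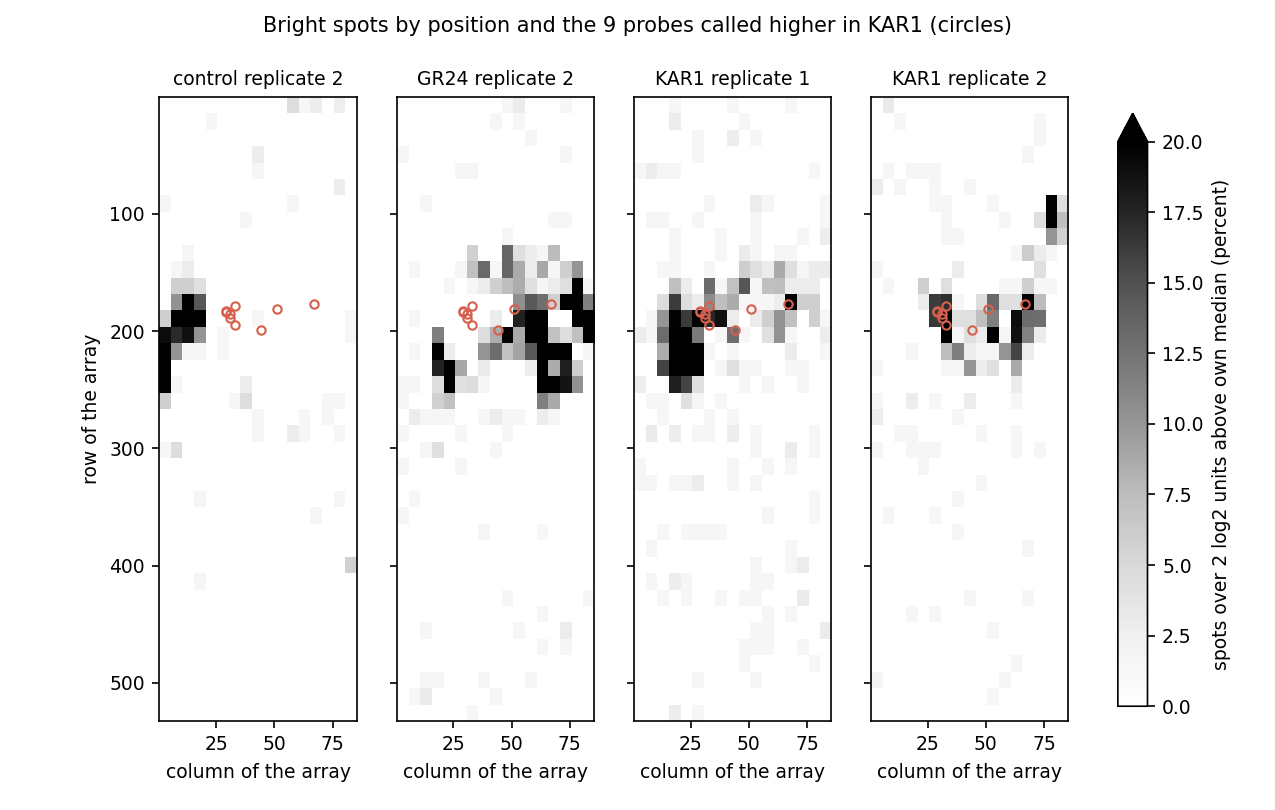
Share of spots more than 2 log2 units above their own median across arrays (grey scale, percent, topped at 20) in blocks of 14 rows by 5 columns, drawn over the rows and columns of 4 arrays, with circles at the 9 probes called higher in KAR1. The circles fall between rows 177 and 199, where both KAR1 arrays have dark blocks.

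Among described genes filled in by unadjusted p, none of which passed over all probes, IAA13 (A_95_P026156), of the Aux/IAA family of auxin response repressors, had 1.42 in KAR1 (SE 0.22, adjusted p = 0.292), 2.68-fold higher. Its GR24 and smoke water means lay within 0.05 log2 units of control. Its spot, at row 189 and column 38, lies among the 9 called higher and was locally bright on 1 of 2 KAR1 arrays. With that spot missing A_95_P026156 had 1.54 (adjusted p = 0.643). The others higher in KAR1 were an expressed protein like At2g22720 (A_95_P031066; 1.45, 2.72-fold, locally bright on KAR1 2 and 1.24 with that spot missing), the peroxidase precursor (A_95_P200402; 3.45, at least 2.38-fold, locally bright on KAR1 1 and 2.74 with that spot missing), the cDNA-AFLP fragment BSTT23-4-290 (1.89, at least 2.91-fold, in an area bright on both KAR1 arrays) and an At5g38660-like gene (1.18, at least 2.15-fold). Lower ones were ribosomal protein L7 (-1.07, 2.10-fold), 1-aminocyclopropane-1-carboxylic acid oxidase, which makes ethylene (A_95_P029796; -2.05, at least 1.82-fold, locally bright on control 2 and -1.88 with that spot missing), diphenol oxidase (A_95_P147147; -2.14, at least 2.01-fold, locally bright on control 1 and -2.34 with that spot missing), adenylate kinase family-like protein (-1.25, 2.38-fold) and a polygalacturonase-1 beta subunit (A_95_P190837; -1.08, 2.11-fold).

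Light harvesting and photosystem genes shifted up in KAR1, with a median log2 difference of 0.40 (56 of 62 higher, adjusted p = 0.00158 with the preset correlation, 0.970 with an estimated correlation). All 27 chlorophyll a/b-binding protein genes, which carry the antenna pigments, were higher in KAR1, by 0.30 to 1.96 (median 0.73), with medians of 0.008 in GR24 and -0.043 in smoke water, and 23 of 26 other photosystem genes were higher. No scaling turned the list's direction. Genes chosen after their values were seen were Cab40 (0.88, SE 0.78), Cab21 (0.75, SE 0.75), Lhcb4, also called CP29 (0.65, SE 0.46), and A_95_P176552 (1.96, SE 1.21), and photosystem I psaH had 0.40 (SE 0.36). The 3 members with the smallest p matched only through a protein accession starting with CAB and are not known light harvesting genes: CAB62118.1 (-0.76, at least 1.08-fold lower), CAB66399.1 (0.84) and CAB53482.1 (0.40). With 9 such members left out the median was 0.43 (adjusted p = 0.000563). Chlorophyll synthesis genes had a median of 0.38 (11 of 12 higher, adjusted p = 0.0366 with the preset correlation, 0.970 with an estimated correlation), including NADPH:protochlorophyllide oxidoreductase at 0.60 (SE 0.37) and POR2 at 0.84 (SE 0.58). Organelle-encoded genes had 0.30 (9 of 9 higher, 0.0366 with the preset correlation, 0.970 with an estimated correlation), with psaC at 0.30 (SE 0.20). 5 of these 9, psaH among them, are nuclear photosystem genes, and the 4 left are too few to test. No member of the 3 lists passed alone, adjusted over the list alone or over all probes.

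These 3 shifts followed the array sets. Without control 1, the only control array of set 1, the light harvesting median was -0.04 (adjusted p = 0.882), chlorophyll synthesis 0.04 (0.882) and organelle-encoded 0.04 (0.717), which are also the values within set 2. Without control 2 they were 0.88, 0.83 and 0.65. Light harvesting did not pass without KAR1 2 (0.28, 0.152), chlorophyll synthesis without KAR1 1 (0.38, 0.208) or KAR1 2 (0.36, 0.152), and organelle-encoded without KAR1 2 (0.10, 0.578), while without KAR1 1 it was 0.46. With the sets as a block the medians were 0.02 (0.937), 0.13 (0.480) and 0.11 (0.522), and with no dim filter 0.35 (0.293), 0.37 (0.293) and 0.25 (0.167). Organelle-encoded also ended with quantile normalization (0.23, 0.0838), alone or after normexp (0.21, 0.0996). Set 1 holds no KAR1 array, so no value within it can be had.

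**Figure D3:**
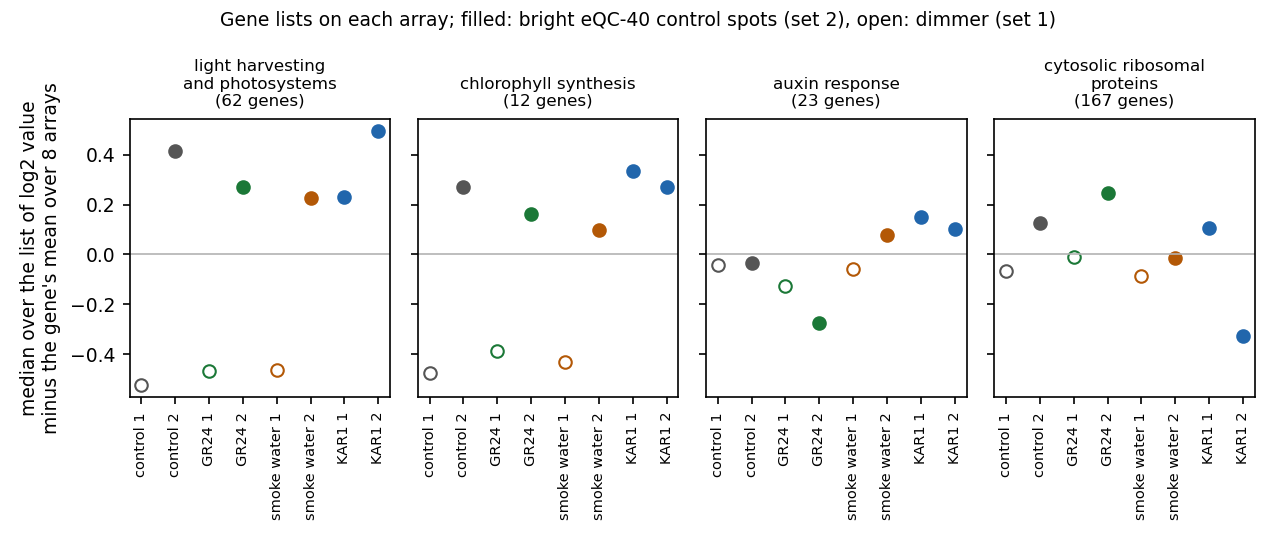
Median over each list of a gene's log2 value minus its mean over the 8 arrays (y axis), with 1 point per array (x axis), colours for groups, filled points for the 5 arrays of set 2 and open points for the 3 arrays of set 1. In light harvesting and chlorophyll synthesis the 3 open points lie apart from all filled ones, and in auxin response they do not.

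Auxin response genes shifted up in KAR1, with a median of 0.33 (17 of 23 higher, adjusted p = 0.0240 with the preset correlation, 0.970 with an estimated correlation). IAA13 alone passed adjusted over the list alone, also with its bright spot missing, and none passed over all probes. Nt-gh3, of the family that couples auxin to amino acids, had 1.15 (SE 0.40, 2.21-fold). With the array sets as a block the median was 0.29 (0.0432), and within set 2 it was 0.34. The shift did not pass without control 2 (0.15, 0.139) or KAR1 1 (0.13, 0.108), was 0.20 (0.0496) without KAR1 2, and with locally bright spots missing was 0.28 (0.0883), with the block as well 0.23 (0.180) and with no dim filter 0.25 (0.561). Ribosomal protein genes shifted down, with a median of -0.12 (115 of 167 lower, adjusted p = 0.0305 with the preset correlation, 0.970 with an estimated correlation), -0.16 (0.00224) without the 24 mismatched members, and -0.23 (8.83e-05) with the array sets as a block. None passed alone, adjusted over the list alone or over all probes. Of its examples, 3 are not cytosolic: an L33-like protein (-1.41, at least 2.65-fold lower, 1 of 2 KAR1 arrays above background), a bacterial-type L17 (1.49, 2.81-fold higher) and chloroplast S9 (0.70). The median turned to 0.07 (adjusted p = 0.311) without KAR1 2, was -0.0011 (0.970) without control 2, -0.24 without control 1 and -0.35 without KAR1 1. With locally bright spots missing it was -0.12 (0.0573).

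KAR1 against GR24 sets 2 compounds with a butenolide ring, given at one concentration, against each other on slide 2, with the spread estimated over all 8 arrays, controls included. Here 8 probes were higher in KAR1 and none lower (limma, 2063 at an unadjusted p under 0.05, 38.7% without overlap against 33.3% by chance). All 8 are among the 9 called higher against control, and the glycine-rich protein-like gene, the only described one, had 4.60 (95% interval 3.66 to 5.54, adjusted p = 0.040), at least 7.29-fold. Its spot lies in an area bright on both KAR1 arrays. With locally bright spots missing 2 probes passed, A_95_P231819 and A_95_P274583, neither of which had such a spot. With the array sets as a block 2 passed, A_95_P159872 and A_95_P231819. The cystinosin homolog and A_95_P094308, low in both groups, did not pass here. Described genes filled in by unadjusted p, none of which passed, were higher in KAR1 for IAA13 (1.42, interval 0.90 to 1.94), cullin 1B (2.17, interval 1.28 to 3.06, at least 2.53-fold), solanesyl diphosphate synthase 1 (1.12, interval 0.64 to 1.60), a CP5-like gene (1.35, interval 0.70 to 2.01) and the protein CAA32025.1 (1.56, interval 0.82 to 2.29). They were lower for origin recognition complex subunit 6-like (-1.74, interval -2.53 to -0.95), C-7 protein (-1.18, interval -1.83 to -0.52), a glutathione S-transferase (-1.37, interval -2.18 to -0.57, at least 1.49-fold), a ubiquitin fusion protein (-1.76, interval -2.81 to -0.70, at least 3.26-fold), a transcription factor (A_95_P146197; -1.17, interval -1.89 to -0.46) and a hydrolase (A_95_P087698; -1.15, interval -1.81 to -0.49). Without GR24 1, GR24 2, smoke water 1 or smoke water 2 in turn, 0 probes passed by limma, without control 1 or control 2 3, and without KAR1 1 or KAR1 2 15. With the spread taken from the GR24 and KAR1 arrays alone, 0 passed (1386 at an unadjusted p under 0.05), as with normexp background correction (1889), normexp and quantile normalization (2232), probes above background on all 8 arrays (1932), or trend and robust variances (2112). The filter on all 8 arrays leaves all 8 called probes untested, so it does not bear on their calls. No dim filter gave 2 and the replicate block 3.

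Of the lists, 7 shifted between KAR1 and GR24, each with an adjusted p of 0.970 with an estimated correlation. With no dim filter ribosomal genes alone passed, and the other 6 had adjusted p of 0.238 to 0.717. Auxin response was higher in KAR1 by a median of 0.49 (20 of 23, adjusted p = 0.0015), kept passing without each of the 8 arrays in turn, and was 0.39 (0.00417) with the array sets as a block and 0.32 (0.0146) with locally bright spots missing. Leaving out a control or smoke water array changes only the estimated spread here, so those fits do not test the shift itself. IAA13 passed adjusted over the auxin response list alone, and Nt-gh3, chosen after its values were seen, had 0.93 (interval -0.02 to 1.89). Light harvesting was higher by 0.50 (54 of 62, 0.0009), with Cab40 at 0.83 (interval -1.05 to 2.71) and Cab21 at 0.75 (interval -1.06 to 2.55). It was 0.09 (0.672) without GR24 1, the only GR24 array of set 1, and within set 2, 0.87 without GR24 2, and 0.05 (0.760) with the sets as a block. Chlorophyll synthesis was higher by 0.46 (12 of 12, 0.0284), and was 0.17 (0.449) without GR24 1, 0.83 without GR24 2, 0.41 (0.157) without KAR1 1, 0.40 (0.0829) without KAR1 2, 0.15 (0.378) with the block and 0.28 (0.0641) with normexp and quantile normalization. Organelle-encoded was higher by 0.41 (9 of 9, 0.0224), and was 0.17 (0.315) without GR24 1, 0.20 (0.311) without KAR1 2, 0.14 (0.302) with the block and 0.22 (0.0838) with quantile normalization, or 0.18 (0.0546) after normexp.

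Light signalling and clock genes were higher in KAR1 than in GR24 by a median of 0.23 (16 of 20, adjusted p = 0.0240), with COP1-like protein at 1.45 (interval 0.51 to 2.39) and the clock gene PRR5-like at 1.70 (interval 0.44 to 2.97), both chosen after their values were seen. The shift was 0.46 without GR24 1, did not pass without GR24 2 (0.17, 0.415) or KAR1 1 (0.36, 0.0844), and was 0.37 (0.00417) with the array sets as a block and 0.21 (0.0689) with locally bright spots missing. Sugar and starch genes were higher by 0.28 (21 of 33, 0.0385), including the sucrose-phosphate synthases SPSB at 1.20 (interval 0.51 to 1.89) and SPSC at 0.83 (interval 0.32 to 1.35), likewise chosen afterwards. That shift did not pass without GR24 1 (0.24, 0.161) or KAR1 1 (0.21, 0.459), with the sets as a block (0.18, 0.323) or with bright spots missing (0.34, 0.0732), nor with the replicate block (0.28, 0.0625), probes above background on all 8 arrays (0.26, 0.0570) or all probes of a gene (0.29, 0.0597). Ribosomal protein genes were lower by a median of -0.22 (132 of 167, 0.0015), -0.36 without GR24 1, -0.07 (0.407) without GR24 2, -0.46 without KAR1 1 and 0.0022 (0.942) without KAR1 2. With the sets as a block they had -0.31. Over the members of these 7 lists, no other gene passed adjusted over its list alone, and none passed over all probes.

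Smoke water against KAR1 asks whether smoke water, which holds KAR1, differed from the compound alone. It gave 10 probes, 8 of them lower in smoke water and all among the 9 called higher in KAR1 against control, and 2 higher: the cystinosin homolog (2.69, SE 0.25, adjusted p = 0.045), at least 1.67-fold, and A_95_P094308 (3.55, SE 0.26, adjusted p = 0.023), at least 3.74-fold (limma, 1198 at an unadjusted p under 0.05). Smoke water against GR24 gave A_95_P094308 alone, higher in smoke water by 4.20 (SE 0.26, adjusted p = 0.040), at least 4.90-fold (456 at an unadjusted p under 0.05), and the call ended without any of the 8 arrays in turn. By limma it was 0 with the array sets (1026 at an unadjusted p under 0.05) or the replicate numbers (663) as a block, with bright spots missing as well as the sets (1004), quantile normalization (432), normexp (209), both (304), no dim filter (1235), probes above background on all 8 arrays (320), only the 2 groups (466), trend and robust variances (373), or both KAR1 arrays left out (531). For smoke water against KAR1, 4 probes passed without control 1 or control 2, 2 without GR24 1 or GR24 2, 0 without smoke water 1 or smoke water 2, 15 without KAR1 1 and 16 without KAR1 2. With locally bright spots missing 3 passed, A_95_P094308 among them and the cystinosin homolog not, with the array sets as a block 2, both lower in smoke water, and with both 1. It gave 2 with no dim filter, 3 with the replicate block, and 0 by limma with normexp (1022 at an unadjusted p under 0.05), normexp and quantile normalization (1189), probes above background on all 8 arrays (1052), only the 2 groups (845), or trend and robust variances (1188). In both comparisons the filter on all 8 arrays leaves every called probe untested, so it does not bear on their calls. The F test across the 4 groups gave 9 probes (925 at an unadjusted p under 0.05), 2 with bright spots missing, 3 with the array sets as a block, 3 with array weights, 1 with the replicate block, 13 without KAR1 1, 5 without KAR1 2 and 0 by limma without any other array, with normexp, alone or with quantile normalization, with no dim filter, with probes above background on all 8 arrays, or with trend and robust variances.

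Whether the treatments moved the same genes was asked across 22909 probes, which are not independent replicates. Differences from control correlated at 0.51 for GR24 and smoke water, 0.24 for GR24 and KAR1 and 0.45 for smoke water and KAR1, where 100 simulations of unchanged groups against the same controls gave 0.50, 0.50 and 0.50. The simulations drew each array independently, and the array sets widened their spread. In the data, control, GR24 and smoke water share the sets by replicate number, and both KAR1 arrays are in set 2. A value below the simulated one therefore does not show unlike responses. Covariances were 0.0456, 0.0338 and 0.0568 against 0.0890, 0.0884 and 0.0886 simulated, and the same sign was seen at 68.1%, 53.8% and 62.1% of probes against 66.7%, 66.6% and 66.6%. A_95_P094308, lower in GR24 and KAR1, was the only probe called for 2 treatments, where independent calls would share 0.000174. With the array sets, which control, GR24 and smoke water share by replicate number, as a block, covariances were 0.0456, 0.0165 and 0.0457 against 0.0492, 0.0494 and 0.0493 simulated. GR24 and KAR1 then correlated at 0.12, with the same sign at 49.8% of probes. The simulated values came from plain group means, not from the block fit, so for pairs with KAR1 they are not a like reference. The controls were not split, as each part would hold 1 array, so likeness due to the shared controls was not separated from likeness between treatments.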

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

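The criterion for these tests of control spots, and both scales they were made on, were chosen after the values of those spots were seen. Spike-in spots, which carry no plant gene and enter no comparison, were brighter on the raw log2 scale in a treated group when its dimmer array lay above the brighter control array by more than the range of both controls. That was so for E1A_r60_a20 in GR24 (0.127 above control), E1A_r60_a22 in GR24 (0.0969), E1A_r60_1 in GR24 (0.163) and KAR1 (0.0665), and E1A_r60_n9 in GR24 (0.279) and KAR1 (0.162). These are 6 of 30 pairs of a control spot and a treatment (10 kinds of spots, 3 treatments). After each array's 75th percentile was subtracted, 0 of the 30 pairs met the same criterion, a count with no test. No group has 4 or more arrays, so no array was checked against the others of its group.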

How the results depend on the processing

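Most alternatives were fixed before the data were examined, and those with locally bright spots missing, the array sets as a block, both together, crossed replicate numbers, both KAR1 arrays left out and mismatched list members left out were chosen after seeing the data. Over all alternatives, counts of probes stayed within 1.5 times their value in 70 cases, fell to 0 in 71 and moved further in 33. Counts of lists did so in 81, 5 and 24 cases, and single list shifts kept their direction and call in 319, lost the call in 86 and turned in 4. Of named genes 4022 values kept direction and call, 431 lost the call and 20 turned. A gene called in neither fit counts as kept, as does a count of 0 that stayed 0. The slide and scan blocks, which leave comparisons within a slide unchanged, are counted too. These tallies therefore do not measure how stable the calls are. The authors' series matrix gave the same counts. GR24 minus control gave 0 probes instead of 1 with normexp background correction, with normexp and quantile normalization, with no dim filter, with probes above background on all 8 arrays, with the replicate block, with only its 2 groups and with both KAR1 arrays left out, and 2 with the array sets as a block and locally bright spots missing. KAR1 minus control gave 0 instead of 13 with normexp background correction, normexp and quantile normalization, no dim filter, probes above background on all 8 arrays, only its 2 groups, and trend and robust variances, 3 with the replicate block, 7 with locally bright spots missing, 2 with the array sets as a block and 1 with both. None of the 4 lower probes passed with the replicate block or with the array sets as a block. KAR1 minus GR24 gave 0 instead of 8, and smoke water minus KAR1 0 instead of 10, with normexp background correction, normexp and quantile normalization, probes above background on all 8 arrays, only the 2 groups, and trend and robust variances. Each gave 2 with no dim filter, 3 with the replicate block and 2 with the array sets as a block, 1 with that block and locally bright spots missing, and, with bright spots missing alone, 2 and 3. Smoke water minus GR24 gave 0 instead of 1 with quantile normalization, both normexp settings, no dim filter, probes above background on all 8 arrays, the replicate block, only its 2 groups, trend and robust variances, the array sets as a block, the block with bright spots missing, and both KAR1 arrays left out. Of the probes called in pairwise comparisons, the filter on all 8 arrays kept only A_95_P283673 and A_95_P069925. For the others its 0 was fixed in advance. The F test gave 0 instead of 9 with both normexp settings, no dim filter, probes above background on all 8 arrays, and trend and robust variances, 1 with the replicate block, 3 with array weights, 4 with crossed replicate numbers, 2 with bright spots missing, 3 with the array sets as a block and 2 with both. Leaving out each array in turn, where a lone array is assumed to vary like the other groups, gave 0 to 0 probes for GR24 minus control, 0 to 18 for KAR1 minus control, 0 to 15 for KAR1 minus GR24, 0 to 16 for smoke water minus KAR1, 0 to 0 for smoke water minus GR24 and 0 to 13 for the F test. Lists past the threshold in GR24 minus control were 2 instead of 1 with quantile normalization, both normexp settings and mismatched members left out, and 3 with probes above background on all 8 arrays. In smoke water minus control they were 0 instead of 2 with no dim filter. In KAR1 minus control they were 8 instead of 5 with normexp background correction, 1 with no dim filter, 3 with bright spots missing, 2 with the array sets as a block and 2 with both, and in KAR1 minus GR24 1 instead of 7 with no dim filter and 4 with the block, alone or with bright spots missing. An estimated correlation gave 0 lists in each comparison. Without each array in turn, lists numbered 1 to 4, 1 to 5, 2 to 6 and 3 to 7 in these 4 comparisons. The median of all genes was -0.18 in GR24 and KAR1 minus control with median scaling, against 0.01 and -0.01, and with no dim filter -0.10 in smoke water minus control, 0.12 in KAR1 minus control and 0.18 in KAR1 minus GR24, against -0.02, -0.01 and -0.02. Shifts that turned without an array were ribosomal genes (smoke water -0.21 to 0.0066; KAR1 -0.35 to 0.0743; KAR1 minus GR24 -0.46 to 0.0022) and light harvesting genes in KAR1 (-0.0447 to 0.88). Genes that turned so, none of them past the threshold, were A_95_P207657 (-0.11 to 0.56), ornithine decarboxylase A_95_P122017 (-0.97 to 0.0471), Cab40 (-0.0301 to 1.78) and Cab21 (-0.0523 to 1.56) in KAR1, Cab21 in KAR1 minus GR24 (-0.0773 to 1.57), CRK1 (-0.92 to 0.65) and vicilin-like A_95_P010226 (-1.92 to 0.44) in GR24, and caffeoyl-CoA O-methyltransferase 3 (-0.47 to 0.94) and PAL1 (-0.23 to 0.91) in smoke water. With normexp background correction the FLK-like gene in GR24 had -0.0359, the ethylene-induced cDNA A_95_P206377 -0.0461, A_95_P014191 -0.0115, and caffeoyl-CoA O-methyltransferase 3 in smoke water -0.0139, or -0.0099 with quantile normalization added. Rubisco activase in KAR1 had -0.0111 with quantile normalization and -0.0401 with both, and Cab21 in KAR1 minus GR24 had -0.0069 with the array sets as a block. The covariance of GR24 and smoke water was 0.02995 with probes above background on all 8 arrays and 0.0403 with quantile normalization, against 0.0456. For GR24 and KAR1 it was 0.0144, 0.0301, 0.0304 with bright spots missing and 0.0165 with the block, against 0.0338, and for smoke water and KAR1 0.0403 with probes above background on all 8 arrays and 0.0457 with the block, against 0.0568. The replicate block changes the sugar and starch shift in KAR1 minus GR24 to an adjusted p of 0.0625. Differences between replicate 1 and 2 correlated at 0.65 to 0.77 among control, GR24 and smoke water and at -0.28 to -0.19 with KAR1, so the numbers are not established as a pairing. The slide block fits only comparisons within a slide. For the changes listed here the cause was not tested, except that fewer arrays leave less to estimate the spread from. Signal over background limits the dim probes, for which folds are bounds.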

Other observations

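Hormone lists other than auxin did not pass in any comparison, given here as medians in the order GR24, smoke water and KAR1 against control and KAR1 against GR24. Gibberellin genes (9) had -0.06, -0.04, -0.17 and -0.11 (adjusted p = 0.790, 0.807, 0.790 and 0.931), with GA2ox1, an enzyme that inactivates gibberellins, at 0.84 (SE 0.22) in KAR1. Between KAR1 and GR24 it was the only member to pass adjusted over the list alone. Ethylene genes (29) had -0.11, -0.01, -0.05 and -0.07 (adjusted p = 0.705, 0.981, 0.972 and 0.871), and in KAR1 1-aminocyclopropane-1-carboxylic acid oxidase was the only member to pass adjusted over the list alone, but not with its locally bright spot on control 2 missing (0.124), while the receptor NTHK2 had 1.26 (SE 0.35). Abscisic acid and dehydration genes (12) had 0.04, 0.05, -0.18 and -0.11 (0.819, 0.947, 0.418 and 0.807), with DREB3 at 1.19 (SE 0.31) in KAR1. Brassinosteroid genes (8) had -0.05, -0.10, 0.06 and 0.10 (0.502, 0.864, 0.947 and 0.591), and jasmonate and wounding genes (21) 0.11, 0.04, 0.05 and -0.05 (0.526, 0.807, 0.819 and 0.901). Auxin response had -0.15 in GR24 (0.205) and -0.02 in smoke water (0.666). The 4 cytokinin genes, too few to test, had in GR24, smoke water and KAR1 0.51, 0.08 and 0.75 (cig1), 0.08, 0.17 and 0.22 (zeatin O-xylosyltransferase), -0.07, -0.17 and 0.32 (cytokinin dehydrogenase 7) and -0.14, 0.07 and 0.0049 (CRK1). Carotenoid cleavage dioxygenase 1B had 0.28 between KAR1 and GR24.

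Among growth and metabolism lists, Calvin cycle genes (11) had -0.07, -0.18, 0.29 and 0.34 in the same order (adjusted p = 0.947, 0.194, 0.145 and 0.184), with the small Rubisco subunit RBS1 at 0.64 (SE 0.22) in KAR1. Cell wall loosening genes (30) had -0.09, -0.05, -0.10 and -0.13 (0.666, 0.502, 0.0905 and 0.269), cell cycle and histone genes (45) 0.02, -0.04, 0.08 and 0.11 (0.871, 0.718, 0.742 and 0.807), and nitrate and phosphate genes (24) 0.04, -0.07, 0.24 and 0.21 (0.790, 0.871, 0.211 and 0.145), with the phosphate transporter NtPT2 at 1.46 (SE 0.60) in KAR1. Lipid transfer and cuticle genes (12) had 0.07, -0.04, -0.04 and -0.11 (0.950, 0.947, 0.947 and 0.947), root-enriched nicotine genes (10) 0.29, -0.06, 0.02 and -0.17 (0.502, 0.852, 0.871 and 0.819), and flower and pollen genes (21) 0.11, -0.04, 0.01 and -0.02 (0.807, 0.864, 0.807 and 0.919). Light harvesting had -0.04 in GR24 (0.526) and -0.07 in smoke water (0.505), chlorophyll synthesis -0.09 (0.807) and -0.09 (0.345), organelle-encoded -0.07 (0.567) and -0.05 (0.765), and sugar and starch -0.09 (0.148) and -0.0030 (0.819), with 0.18 in KAR1 (0.255). Light signalling and clock had -0.04 in smoke water (0.833) and 0.12 in KAR1 (0.705), and ribosomal genes 0.08 in GR24 (0.145). Of the seed storage list, too few to test, the vicilin-like gene had -0.74, -0.37 and 0.47 in GR24, smoke water and KAR1. Its other 2 members are an immunoglobulin match (-0.11, -0.18 and -0.09) and the chloroplast protein plastoglobulin 1 (-0.14, -0.17 and 0.32), which are not seed storage proteins.

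Stress and defence lists did not pass either. Pathogenesis-related and defence genes (77) had 0.09, 0.09, 0.15 and 0.11 (adjusted p = 0.591, 0.0615, 0.178 and 0.591), detoxification enzymes (72) 0.07, 0.06, -0.03 and 0.09 (0.852, 0.178, 0.819 and 0.913), and heat shock proteins (64) 0.03, -0.02, -0.01 and 0.01 (0.819, 0.900, 0.871 and 0.950). Oxidative stress enzymes (57) had 0.10, -0.07, 0.08 and 0.01 (0.819, 0.591, 0.505 and 0.765), and in KAR1 the peroxidase precursor was the only member to pass adjusted over the list alone, but not with its locally bright spot on KAR1 1 missing (0.160). Phenylpropanoid genes had 0.08 in GR24 (0.819), 0.21 in KAR1 (0.0905) and 0.14 between KAR1 and GR24 (0.211). Median, mean and test differed in sign for lipid transfer in all 4 comparisons, ethylene in all but GR24, abscisic acid, cell wall and heat shock in GR24, nitrate and phosphate in GR24 and smoke water, auxin, light signalling, nicotine and flower genes in smoke water, brassinosteroid and detoxification in KAR1, and gibberellin, heat shock and flower genes in KAR1 minus GR24.

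The tests weighed next were chosen after the results were seen, except those of light harvesting genes with the array sets as a block and with bright spots missing, written down before their values were computed. Of the 9 probes called higher in KAR1, 66.7% lie in local areas bright on both KAR1 arrays, which may account for those 6. A_95_P231819, A_95_P274583 and A_95_P211557 lie outside such areas as defined here, but in the same region of the array. On KAR1 1, 7.59%, 3.80% and 3.75% of their neighbours were bright, against 1.45% of all spots. On KAR1 2 the shares were 5.06%, 6.33% and 17.5%, against 0.968%. The first 2 had no spot set to missing, so keeping their calls does not test the explanation. A_95_P211557 had 3.14 with its KAR1 2 spot missing, against 2.86 with it. For each of these probes the explanation stays open. Other probes matched to the same transcripts number 2, too few to tell whether KAR1 raised these transcripts. Of these, A_95_P235364, well above background on both arrays of at least 1 group, had 0.23 where the called probe had 4.75. A_95_P159852 had 0.15 where A_95_P159872 had 3.86, from control means of -7.32 and -7.36. A_95_P159852 stayed at background in KAR1, and whether it can detect the transcript was not tested.

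For light harvesting genes in KAR1, the uneven spread of the 2 array sets over the groups is a candidate explanation, since the median was 0.0182 with the sets as a block. Local bright areas are unlikely to account for it, as the median was 0.44 with bright spots missing. A larger share of leaf tissue in KAR1 seedlings may also raise these genes. Its prediction, that Calvin cycle and chlorophyll synthesis genes shift up too, was met, with a Calvin cycle median of 0.29. The block cannot decide this: light harvesting genes differed by 0.74 between the sets, and a tissue difference between them would be removed with the block. What the sets stand for, such as trial, was not tested. The block also rests on placing KAR1 2 in set 2 by its eQC-40 spots. Across all probes its correlations with the 2 sets overlapped. For light harvesting genes it did lie with set 2. Their median log2 value, minus each gene's mean over arrays, was 0.49 on KAR1 2. It was 0.23 to 0.41 on the other set 2 arrays and -0.52 to -0.47 on those of set 1. Both slides hold arrays of both sets, so neither the slide nor its scan accounts for the split. The labels give 21 days after germination for every group.

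For the pairing of GR24 and KAR1 against control and smoke water, 6 probes were called against 0 for each of the other 2 pairings, while 723 had an unadjusted p under 0.05 against 995 and 1056 (limma). Of the 6, A_95_P159872 and A_95_P231819 were high in KAR1 alone and at the floor in GR24. Neither an effect on the whole slide nor a response to both butenolides could therefore give them. Both lie in the region where spots were bright on the KAR1 arrays, so a local effect on part of the slide stays open. The other 4 were lower in GR24 and KAR1, and local bright areas on control and smoke water arrays are unlikely there, with 0 of them in such an area. For these 4, slide and a response to both butenolides cannot be told apart. A_95_P177157, matched to A_95_P283673 by shared sequence or name and well above background, had -0.20 in KAR1 where the called probe had -2.01. In control they lay at 5.57 and -1.24, so both may not read the same transcript.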
